A study of Mus musculus with 4 samples.

How the data were processed

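RNA of newborn mouse lenses was measured on Affymetrix mouse expression arrays, with 1 array per sample, 2 wild-type and 2 Hsf4 knockout samples. Per the labels' protocols, lenses were kept in a stabilising solution, RNA was isolated on columns with DNase digestion, and biotin-labelled targets were made by oligo-T7 reverse transcription. The values used are the intensities the authors deposited, 1 per probe set and array, on a linear scale. The software that summarised the probes and its background correction are not given in the sources used here. The deposited intensity values were not normalized between arrays, since their trimmed means ranged from 21.4 to 96.2 and their medians from 6.58 to 21.4.

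The planned analysis took log2(intensity + 16) of the values as deposited. Because the deposited values were linear and differed in scale, they were instead quantile normalized with limma 3.58.1 in R 4.3.3, an offset of 16 was added and log2 was taken; the values as deposited were kept as an alternative. The 64 control probe sets were left out after normalization. Of the 45037 others, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 had none, and no gene was named from a probe set with several. Each of 18193 genes was represented by its probe set with the highest mean. Probe sets and genes were tested where the mean log2 value reached the median over the non-control probe sets, 4.86, or an intensity of about 13.0, which left 22519 probe sets and 11595 genes. Genes of interest without a probe set in that annotation were not analysed here.

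Groups were compared with limma's linear model and moderated test with a trend of the variance on intensity, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A count of genes at least 2-fold apart whose groups do not overlap was made beside it. The 28 gene lists, among them markers of other cell types, and the rule for named genes were fixed before the data were examined. Lists with at least 3 genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The rule for named genes selected Hsf4, all crystallin genes and the 10 genes with the lowest p in each direction (as fewer than 5 passed the threshold in either). It also took up to 4 passing members of each list or otherwise the 2 with the lowest p. Only some of the selected genes are described below, a choice not fixed beforehand. Psmd6, Hspb8, Hspa8, Hspa9, Hspd1, Hspe1, Serpinh1, Mip, Gja3, Lim2, Dcn, Lum, Rgs5, Hba-a2, Eif2s3y, Bfsp2 and the genes of the second muscle list fall outside that rule and were named after their values were seen.

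The labels give both groups the numbers 1 and 2 without saying that a number marks a shared litter or day. Arrays of different numbers differ in scale and in their ribosomal RNA control probe sets, so the number may mark a technical batch. The main fit had no block for it. Changes within each number and with the number as a block are given beside the pooled values.

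The procedure was tested on simulated data for 22519 probe sets, 10 simulations with 200 changed probe sets each. The first simulation used each probe set's moderated variance. It called 10.2% of 2-fold, 91.9% of 4-fold and 99.8% of 8-fold changes, and 9.29% of its calls were false, above the threshold. A second simulation, added after that result was seen, drew the variances from the fitted prior distribution. It called 0.666%, 29.1% and 76.9%, with 5.29% of calls false. The share of changes recovered thus depends strongly on the noise model, and both are given. Muscle markers lowered by a log2 of 1 were called as a list in 10 of 10 simulations under both noise models, with 0.769% and 0.385% of the other lists called. The simulated noise was independent between probe sets and had no effect of the array number. In the data the members of the muscle list had an estimated correlation of 0.69. These list rates therefore do not measure how often camera calls a list falsely on these arrays. The alternatives were values as deposited, quantile normalization after the log, median centring, no filter and a filter at the 70th percentile, offsets of 1 and 64, other variance models, the block, other ways to combine probe sets, and leaving out each array. Scaling by the trimmed mean and the comparison within each number were added after seeing the data.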

Results

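The series compared RNA of whole lenses from newborn mice (postnatal day 0.5) that lacked Hsf4 with that of wild-type mice. Hsf4 encodes heat shock transcription factor 4, a regulator of gene expression in the lens, and the comparison asks which lens RNAs differ when it is absent. Per the labels, all animals were males of the 129S3 background, though the Xist values given below leave the sex of the number 1 samples in doubt. There were 2 arrays per group, numbered 1 and 2 in the labels, and each carried 45101 probe sets. The labels do not say that the samples came from separate animals, so the p-values below measure only the spread between these arrays, which may be technical. The deposited median intensity was 21.4 on wild-type array 1, 18.5 on knockout array 1, 10.5 on wild-type array 2 and 6.58 on knockout array 2, and the arrays were therefore brought to one distribution by quantile normalization. The number of arrays limits the precision. Levels are normalized intensities as mean ± SD (n = 2 per group), and log2 changes are knockout minus wild type on the log2(intensity + 16) scale with the standard error (SE), which understates the change of dim genes. Adjusted p-values are limma's with Benjamini-Hochberg adjustment.

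The only probe set named for Hsf4 in the annotation used here was brighter, not dimmer, on the arrays labelled knockout. Its intensity was 505 and 138 on the arrays labelled wild type 1 and 2, and 1212 and 413 on those labelled knockout 1 and 2. The log2 change was 1.36 (SE 0.59) with an adjusted p of 1, and it was 1.24 within number 1 and 1.48 within number 2. With the array number as a block, a fit whose p-values rest on a variance trend shared by all genes, the adjusted p was 4.47e-09, and without knockout array 2 the change was 2.11 with an adjusted p of 0.000161. It was 2.23 without wild-type array 1, 0.60 without knockout array 1 and 0.47 without wild-type array 2. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here. A probe set outside that part checks nothing, so the labels could not be checked by this gene, and every direction below refers to the libraries as labelled knockout and wild type.

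Genes of striated muscle were far lower on both arrays labelled knockout. Actc1, cardiac alpha-actin, fell from 331 ± 159 to 5.01 ± 4.00, a log2 change of -3.98 (SE 0.38, adjusted p = 0.00719). Myl1, a myosin light chain of fast muscle, fell from 372 ± 165 to 12.7 ± 5.30 (log2 -3.70, SE 0.36, adjusted p = 0.00719), and Acta1, skeletal alpha-actin, fell from 640 ± 381 to 45.9 ± 10.2 (log2 -3.28, SE 0.41, adjusted p = 0.0453). The fast troponins Tnnt3, Tnnc2 and Tnni2 had log2 changes of -2.35, -2.49 and -2.24, and the myosin light chains Mylpf and Myl2 of -2.24 and -2.32, with adjusted p between 0.0587 and 0.175, although a dimmer probe set of Tnni2 had -0.67. All 9 of the 9 muscle markers measured above the filter were lower within both numbers, with a median log2 change of -2.24, and 2 of them passed the threshold over all genes and 9 adjusted over the list alone. The list fell as a set by camera (adjusted p = 8.92e-34). The correlation between its members was estimated at 0.69, and with it the camera adjusted p was 0.498. The correlation alone cannot account for such a loss. For the fibroblast and pericyte list it was estimated at -0.01, yet the unadjusted camera p rose from 4.41e-10 to 0.0229. With an estimated correlation, camera draws its p from the 2 residual degrees of freedom of the 4 arrays. Hardly any list could pass that way, so a failure there says little about a list.

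The fibroblast and pericyte markers also fell as a set (camera adjusted p = 5.96e-09, and 0.498 with an estimated correlation), with a median log2 change of -1.30. Lower values were measured for 7 of the 9 kept members within both numbers, none passed the threshold over all genes, and 5 did so adjusted over the list alone. The fibrillar collagen genes had the largest changes of the list. Col1a1 measured 104 ± 17.3 in wild type and 17.6 ± 5.48 in knockout (log2 -1.84, SE 0.31), while its dimmer probe set had -0.63, and Col3a1 measured 593 ± 165 and 174 ± 84.8 (log2 -1.73, SE 0.37). Dcn and Lum, proteoglycans of the extracellular matrix, had log2 changes of -1.33 and -1.30, while Rgs5, a pericyte gene, had 0.02 and differed in direction between the numbers. Dimmer probe sets of Rgs5 and Col3a1 had 1.50 and -1.48.

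**Figure D1:**
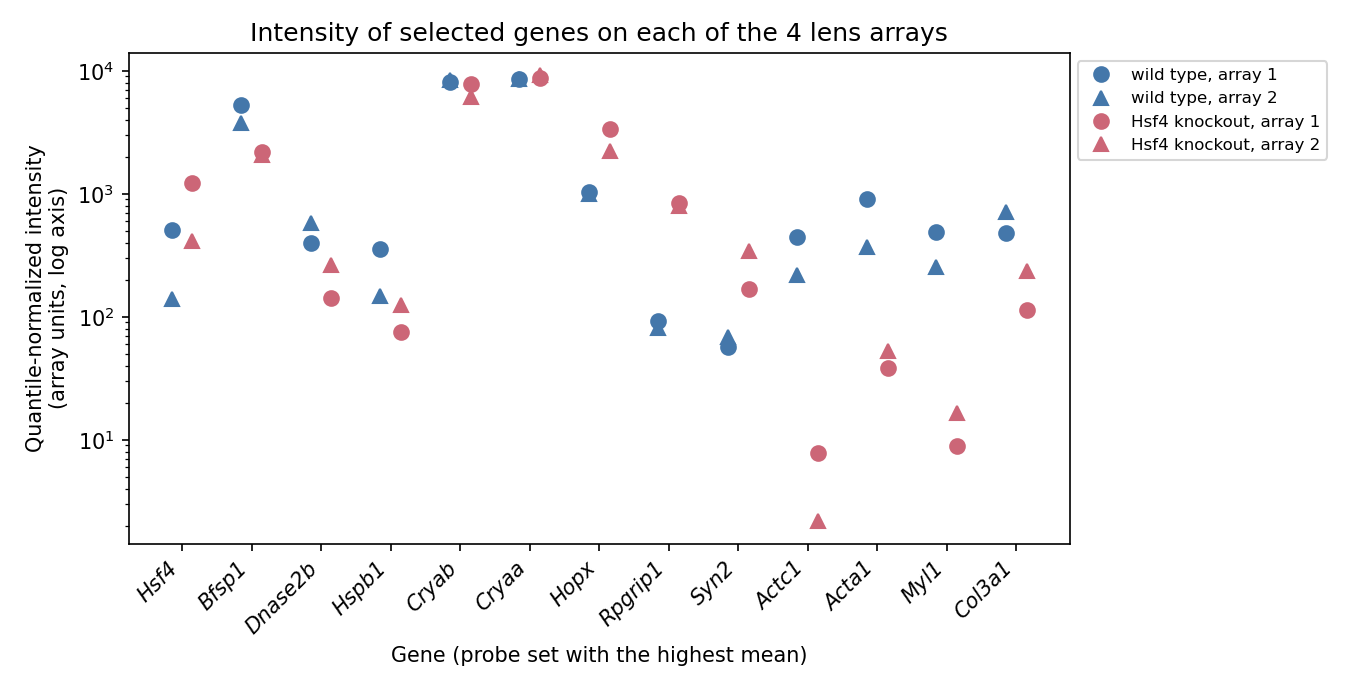
Normalized intensity (log axis, array units) of 13 genes on the 4 arrays, with blue for wild type, red for the arrays labelled knockout, circles for number 1 and triangles for number 2; each point is 1 array. Actc1 lies at 443 and 218 on the wild-type arrays and at 7.84 and 2.18 on the knockout arrays, while Rpgrip1 lies at 93.2 and 80.7 against 836 and 795.

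Across all genes, 4 of the 11595 tested passed the threshold in limma, 1 higher and 3 lower, and 272 had an unadjusted p under 0.05, fewer than chance alone would give. The higher gene was Rpgrip1, a ciliary protein of photoreceptors, at 87.0 ± 8.78 in wild type and 816 ± 28.5 in knockout (log2 3.02, SE 0.28, adjusted p = 0.00719). This rested on 1 of its 4 probe sets, and the only other one above the filter had a log2 change of -0.27. Of the 22519 probe sets tested, 4 passed, and these were the same Rpgrip1 probe set, one each of Actc1 and Myl1, and one of Psmd6, a subunit of the proteasome. The Psmd6 probe set had a log2 change of 3.19 (adjusted p = 0.0354), while the brighter probe set of Psmd6 had 0.26. Groups did not overlap and were at least 2-fold apart for 116 genes, 28 higher and 88 lower. Groups did not overlap for 27.0% of all genes, where chance gives 33.3% if the 4 arrays are exchangeable. The correlation of log2 values was 0.975 between arrays 1 and 0.940 between arrays 2 of the groups. It was 0.951 between the wild-type arrays and 0.923 between the knockout arrays. The 33.3% is thus not a firm reference. With the array number as a block, which leaves 1 residual degree of freedom per gene, limma took the variance wholly from the trend over all genes, so the blocked p-values do not reflect a gene's own spread. In that fit 1057 genes had an unadjusted p under 0.05, against 272 without the block. The threshold was passed by 200 genes, 65 higher and 135 lower, and 14 of these had opposite directions within the numbers. The count was 0 with values as deposited, with no filter and with the mean of all probe sets, 12 with median centring, all lower, 7 with trimmed-mean scaling, 289 without knockout array 1, 61 without knockout array 2 and 8 without wild-type array 2. Rpgrip1 thus lost its call with values as deposited (log2 2.42, adjusted p = 0.994), median centring (2.60, adjusted p = 1), no filter (3.02, adjusted p = 0.0563) and the mean of all probe sets (0.49, adjusted p = 1).

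Below the threshold, the genes with the lowest p among the higher ones included several with more than 1 concordant probe set. Hopx, a homeodomain-only cofactor, measured 1009 ± 26.8 in wild type and 2792 ± 801 in knockout (log2 1.42, SE 0.25, adjusted p = 0.216). Syn2, a synaptic vesicle protein, measured 62.9 ± 7.96 and 255 ± 123 (log2 1.70, SE 0.37), and Gyg, which primes glycogen synthesis, measured 542 ± 23.0 and 1141 ± 88.5 (log2 1.05, SE 0.25). The long noncoding RNAs Rmst and Snhg12 had log2 changes of 1.98 and 1.29, although a dimmer probe set of Rmst had -0.25. Ngdn (log2 1.40, SE 0.33) was measured by a further probe set at 0.09. Crhbp, which binds corticotropin-releasing hormone, had 1.38, and the uncharacterised Gm4792 and 4921507P07Rik had 1.65 and 1.43 from intensities near the floor in wild type. Among the lower genes, Stx11, a syntaxin of membrane fusion, measured 166 ± 3.11 and 22.4 ± 21.0 (log2 -2.36, SE 0.40, adjusted p = 0.175), and its dimmer probe set had -0.98.

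The crystallins, the main soluble proteins of the lens, did not pass the threshold for any of the 14 genes measured. Their log2 changes ranged from -0.26 for Crybb2 to 0.17 for Crybb1. Cryab, a small heat shock protein, measured 8207 ± 234 and 6981 ± 1250 (log2 -0.24, SE 0.17), and Cryaa measured 8512 and 8976 ± 294 (log2 0.08, SE 0.14). Of the 14, 13 ranked within the top 50 probe sets on every array. Quantile normalization sets each value by its rank, so changes among these probe sets were partly fixed by the method. Cryba1, for example, measured 9184 on array 1 and 9805 on array 2 of both groups. The small changes are therefore not a measured absence of change. Whether the signal was also compressed near the upper end of the intensity range was not tested. At its lowest, Cryab lay at 45.9% of its array's maximum. Scaling by the trimmed mean, chosen after seeing the data, moved both crystallin lists to higher in knockout, with mean log2 changes of 0.42 and 0.47, so no direction is given for them.

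In the list of lens fibre structure and junctions, 5 of 15 genes were lower and 4 higher within both numbers, and the list did not pass (camera adjusted p = 0.543). None of its genes passed over all genes tested, and 2 passed adjusted over the list alone, both lower. Bfsp1, filensin of the beaded filament, measured 4502 ± 1015 in wild type and 2123 ± 88.8 in knockout (log2 -1.06, SE 0.21, adjusted p = 0.434), with -1.25 and -0.87 within the numbers. Dnase2b, the nuclease that degrades DNA of fibre cell nuclei, measured 490 ± 126 and 202 ± 84.5 (log2 -1.25, SE 0.35, adjusted p = 1). With the array number as a block the adjusted p of Bfsp1 was 4.10e-12 and that of Dnase2b 7.32e-07. Mip, the main intrinsic protein of fibre membranes, had 0.29, and Gja3 and Lim2 had -0.05 and -0.11. The lens epithelium list (camera adjusted p = 0.956) and the lens transcription factors (camera adjusted p = 0.956) did not pass either. In them Tfap2a and Sox2 had log2 changes of -0.71 and -0.77, with groups that overlapped. Tfap2b of the epithelium list had -0.70, with groups that did not overlap. Tfap2a had -0.26 within number 1 and -1.17 within number 2, Sox2 had -0.55 and -0.99, and Tfap2b had -0.13 and -1.27. The mean log2 change of the fibre list was -0.30 without knockout array 2, and that of the transcription factors was -0.34 without wild-type array 2. With all 4 arrays these means were -0.09 and -0.06, and the camera adjusted p with an estimated correlation was 0.964 and 0.976. For the lens epithelium list and for the alpha and beta crystallins, the mean was below 0 while the median was above it.

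In the list of heat shock proteins and their partners, 13 of 24 genes were lower and 2 higher within both numbers. The list, drawn up as cytosolic, also holds Hspa9, Hspd1 and Hspe1 of mitochondria, which are among the 13, and Serpinh1 of the endoplasmic reticulum. It did not pass (camera adjusted p = 0.0556, and 0.692 with an estimated correlation). Hspb1, a small heat shock protein, measured 250 ± 146 and 99.8 ± 34.6 (log2 -1.12, SE 0.42, adjusted p = 1), with -2.02 within number 1 and -0.21 within number 2. Dnajb1, a cochaperone, measured 693 ± 46.0 and 406 ± 167 (log2 -0.81, SE 0.32, adjusted p = 1). Hspb8 had -0.92 and Hspa8 had 0.28. The list passed under 7 other settings, with adjusted p from 0.00198 with values as deposited to 0.0425 with offset 1. Its adjusted p was 0.00145 without knockout array 2 and 0.821 without knockout array 1. With the array number as a block the list passed (camera adjusted p = 0.0175), as did the cell cycle list (adjusted p = 0.0343, and 0.692 with an estimated correlation in the fit without the block), which newly passed under 7 settings in all. In that list, 13 of 19 genes were lower and 3 higher within both numbers, with a median of -0.26 and a camera adjusted p of 0.0556. The median was -0.11 within number 1 and -0.31 within number 2. Mcm4, a helicase subunit of DNA replication, had the lowest value at -0.65, with -0.15 within number 1 and -1.14 within number 2. Genes that neighbour Hsf4 had a median of 0.21, with 5 of 10 higher and 0 lower within both numbers (camera adjusted p = 0.0556, and 0.692 with an estimated correlation), and the list newly passed under 3 settings.

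Markers of neural retina and of erythroid cells shifted as sets, and neither list passed without knockout array 2. On that array the 3' to 5' signal ratio of control probe sets was 1.89 for actin and 1.05 for Gapdh, against 1.51 to 1.67 and 0.86 to 0.90 on the others. The retina list fell (median log2 -0.42, camera adjusted p = 0.00574, and 0.692 with an estimated correlation), but its median was -0.00 within number 1 and -0.84 within number 2, and the adjusted p was 0.645 without knockout array 2. Neurod4, a transcription factor of retinal neurons, had 0.10 within number 1 and -2.15 within number 2. The erythroid list rose (median 0.97, camera adjusted p = 0.00574, and 0.692 with an estimated correlation), with 3 of 4 genes higher within both numbers, medians of 0.32 and 1.45 within the numbers and an adjusted p of 0.733 without knockout array 2 and 0.0544 without wild-type array 1. Its 4 kept genes included the haemoglobin genes Hbb-b2 and Hba-a2, with log2 changes of 1.07 and 1.03. Hbb-b2 had 0.41 within number 1 and 1.73 within number 2, while Hba-a2 had -0.30 and 2.36. Of the 27 lists tested, 4 passed with the preset correlation of 0.01, and 0 passed with an estimated correlation or by fry in limma, which tests a set alone. The lowest unadjusted camera p with an estimated correlation was 0.0229, for a list whose estimate was -0.01. Those values thus do not single out lists with correlated members. They rest on the 2 residual degrees of freedom of the 4 arrays, so hardly any of the 27 lists could pass that way. The mesenchymal, glycolysis and pigment cell lists had adjusted p of 0.144, 0.122 and 0.177, and the remaining lists had values from 0.406 to 0.956. The mesenchymal list passed as lower by camera with values as deposited (adjusted p = 0.00978) and with median centring (0.00437). Without knockout array 2 its mean log2 change was -0.32, against -0.23 with all 4 arrays. Under the main normalization with all 4 arrays, its camera adjusted p with an estimated correlation was 0.692. Without wild-type array 2, the mean log2 change was -0.49 for glycolysis and 0.85 for pigment cells, against -0.19 and 0.21 with all 4 arrays. With all 4 arrays the camera adjusted p with an estimated correlation was 0.964 for each. Pigment cells passed as higher by camera with offset 1 (adjusted p = 0.0302) and the stricter filter (0.0367).

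**Figure D2:**
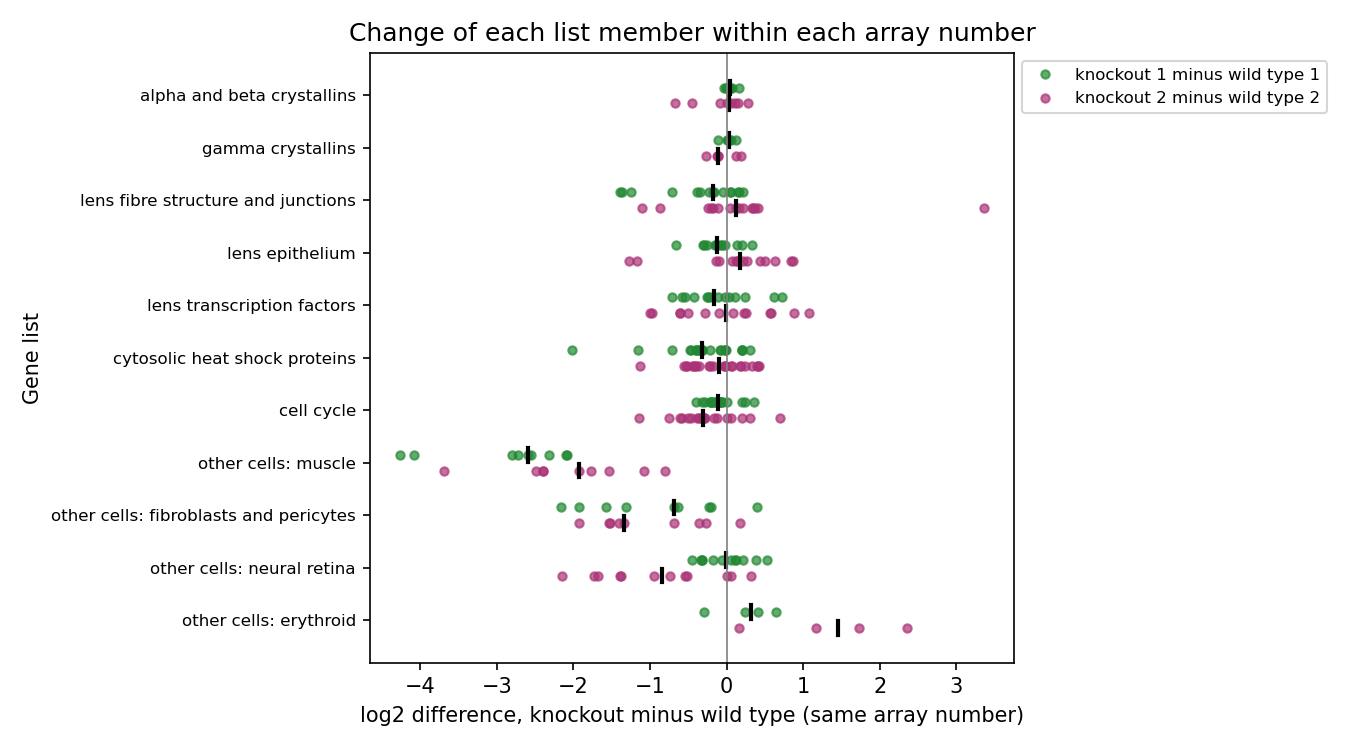
Log2 difference of each list member, knockout minus wild type of the same array number, with green for number 1, purple for number 2 and black bars for the medians. The muscle list has medians of -2.59 and -1.93, and the neural retina list has -0.00 and -0.84.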

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

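The comparison of control probe sets was chosen after the arrays' values were seen. Control probe sets took no part in the tests. After quantile normalization, 6 of those with a mean intensity of at least 13.0 were at least 2-fold brighter on a knockout array than on the brighter wild-type array, all 6 on knockout array 2. One dimmer control, for the middle region of TrpnX, measured 7.50 on knockout array 1 and 0.32 and 1.01 on the wild-type arrays. The 18S ribosomal RNA probe sets of the 3' and middle regions measured 3228 and 3636 on knockout array 2, against 349 and 432 on wild-type array 2, 12.8 and 14.3 on wild-type array 1 and 10.6 and 16.7 on knockout array 1. The 18S probe set of the 5' region measured 7309 on knockout array 2 and 6898 on wild-type array 2. Spike-in probe sets for bioB measured 596, 439 and 519, and one for bioC measured 1197, on knockout array 2, with ratios from 2.02 to 2.85 to wild-type array 2, the brighter wild-type array after normalization. As deposited, bioB measured 207, 150 and 179 on knockout array 2, 153, 125 and 168 on wild-type array 2 and 272, 250 and 275 on wild-type array 1, and bioC measured 447, 452 and 734. The 18S probe sets of the 3' and middle regions measured 1518 and 1780 as deposited on knockout array 2, against 262 and 327 on wild-type array 2. As deposited, knockout array 2 was the dimmest of the 4 arrays, with a median of 6.58.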

How the results depend on the processing

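Scaling by the trimmed mean and the comparison within each array number were chosen after seeing the data; the other alternatives were fixed before. The count of 4 genes became 0 as deposited, 0 with no filter, 0 with the mean of all probe sets, 12 with median centring, 7 with trimmed-mean scaling and 200 with the replicate block, and ranged from 4 to 289 when 1 array was left out. The unadjusted p was under 0.05 for 19 genes as deposited, 550 with no filter and 271 with the mean of all probe sets. The 4 probe sets became 0 as deposited, 0 with no filter, 15 with median centring and 317 with the block, and ranged from 5 to 663. The 116 genes at least 2-fold apart became 68 with the 70th percentile filter, 354 with offset 1, 31 with offset 64 and 68 with the mean of all probe sets, and ranged from 199 to 594; as deposited 3 of 156 were higher and with median centring 4 of 135, against 28 of 116. The 4 lists became 9 with trimmed-mean scaling, 8 with offset 1, 7 with the mean of all probe sets, 0 with an estimated correlation and 0 by fry, and ranged from 4 to 7. Hsf4 kept its log2 change of 1.36 with the block and passed there, and ranged from 0.47 to 2.23. The crystallin lists, with mean log2 changes near 0 (-0.02 for alpha and beta, -0.01 for gamma), passed as higher with trimmed-mean scaling (0.42 and 0.47). Under the main normalization the camera adjusted p was 0.956 for each, and 0.976 with an estimated correlation. The median log2 change of all genes was -0.46 as deposited and -0.28 with median centring. Same-numbered arrays deviated together from their group means over 22519 probe sets (r = 0.429), which does not show pairing with 2 pairs. Among 1395 values of named genes under the alternatives, 83 newly passed, 18 no longer passed and 46 that passed in neither changed sign, 14 of them as deposited. The cause was not tested for any of these changes. A lone array left in a group was assumed to vary like the other group. Dim genes, near the offset, have compressed changes.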

Other observations

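The test of the share of a second muscle list that was lower was chosen before its result was seen, and those of the gap between wild-type arrays (whose first bound was set beforehand and made stricter after the value had met it), of scaling, of Psmd6, of chromosomes and of Hsf4 after. Xist, the RNA that coats the inactive X chromosome, measured 918 and 39.4 as deposited on wild-type arrays 1 and 2 and 359 and 4.48 on knockout arrays 1 and 2, although the labels give all samples as male. The Y-linked gene Eif2s3y measured 95.9 and 153 on the wild-type arrays and 142 and 52.2 on the knockout arrays. Bfsp2, phakinin of the lens beaded filament, measured 180 and 268 on the wild-type arrays after normalization, 60.1 on knockout array 1 and 2907 on knockout array 2.

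Muscle genes were lower on both arrays labelled knockout, and so were 7 of 9 fibroblast and pericyte markers (median log2 -1.30, camera adjusted p = 5.96e-09, and 0.498 with an estimated correlation). A uniform array scale was argued against, since as deposited the muscle list had a median log2 change of -2.40, against -0.46 for all genes. The muscle median relative to all genes was at most -1.94 under 5 scalings. These are not 5 separate checks. Subtracting the median of all genes cancels most of a scale factor, and the values as deposited and median centring both gave -1.94. Muscle tissue carried in the wild-type samples is a candidate explanation: of the 21 kept genes of a second striated muscle list with 47 genes, 61.9% were lower within both numbers, against 27.5% of all kept genes, which lies between the 80% and 50% set beforehand, and 4 (Actn3, Pygm, Cox6a2 and Cox7a1) were higher, with log2 changes from 0.16 to 0.54. The second list had a median log2 change of -0.32 (SD 0.51 over genes), against -2.24 for the first. These medians cannot be compared directly. Many genes of the second list were dim, and the offset of 16 limits how far a dim gene can fall. Myot, for example, fell from 26.9 to 3.47 within number 1, a log2 change of only -1.14. The 61.9% also counts Casq2, Tcap and Casq1, whose changes within number 2 were only -0.0019, -0.0073 and -0.0059. Pgam2, the most abundant gene of the second list, measured 2067 and 1554 on the wild-type arrays and 1595 and 1462 on the knockout arrays. How many genes of the second list lens cells express was not tested. An action of Hsf4 loss within lens cells stays open too and cannot be told apart from carried tissue: the wild-type arrays differed over that list by a median of 0.44, which met the first bound against such an action (at least the size of the median change), but a gap between wild-type arrays does not forbid it, so that test decides nothing.

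Several genes had 1 probe set far higher on both arrays labelled knockout while a brighter probe set of the same gene stayed near 0. Of 38 probe sets at least 2-fold higher with a brighter one beside them, 12 had the brighter one move at least 50% as far. Over both directions this held for 28 of 71. These probe sets were picked for a large change in these same data, and of the 38 only that of Psmd6 passed the threshold. A smaller change of the brighter probe set is thus partly a result of that choice. For Psmd6, a change of the whole RNA was argued against, since the upper 95% bound of the brighter probe set's log2 change was 0.83 against 3.19 for the other. Genes of 1 chromosome segment that differed between the parents were argued against as the source of all 25 such genes. The largest count on 1 chromosome was 4, on chromosome 4, and 65.4% of 10000 random draws reached as many. The draws cannot tell whether a segment lies behind a few of them. Rpgrip1, whose raised probe set was its brightest, was not among the 25. A first run, over all genes at least 2-fold apart, gave 80.1% for the 28 higher and 7.54% for the 88 lower. A change in transcript ends or a strain variant under single probes may remain, as these were not tested.

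The Hsf4 probe set was higher on both arrays labelled knockout. Array scale was argued against, since the lower of the 2 deposited ratios was 1.42 although both of those arrays were dimmer overall. Exchanged labels cannot be told apart from correct ones by the lens fibre list, of which 33.3% were lower and 4 of 15 higher within both numbers. A probe set outside the deleted part was not tested, for lack of the deletion's position.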
